A study of Mus musculus with 4 samples.

How the data were processed

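Whole fetal brains of C57BL/6J mice at embryonic day 16 were compared between 2 pools of fetuses of ethanol-injected females and 2 pools of fetuses of saline-injected females, with RNA of 3 mice in each pool. The deposited values are log2 brightness values, with 1 value per probe set and array. The log base is not stated in the sources used here and was taken as log2 from the range of the values. Partek 6.6 is named in the submitters' processing notes, and the background correction, normalization and summary method are not given in the sources used here. Differences in signal at the dim end can depend on those steps, and the lower quartile of the deposited values was 6.55 on ethanol 1 and 6.45 to 6.47 on the other arrays. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns and labelled as single-stranded cDNA with biotin.

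The table holds 35556 probe sets. Of these, 21789 have 1 gene symbol in the platform annotation, 1621 have several and 12146 have none. Symbols were updated by Entrez identifier through a gene table of assembly GRCm38.p6, in which 21698 of the 21789 were matched, and the other 91 kept the older symbol. No genome build is named in the sources used here, so that table served only for names and for which genes neighbour each other. A gene with several probe sets (999 genes) was represented by the set with the highest mean over all arrays, which left 19938 genes. The table has 0 columns of other samples.

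Ethanol and control arrays were compared with limma 3.58.1 (lmFit and eBayes without trend, in R 4.3.3), two-sided, on the values as deposited, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fit had 2 residual degrees of freedom and 5.65 in total after moderation. Counts were also made at an unadjusted p under 0.05 with a fold of at least 1.2, and of genes whose groups do not overlap. The groups, the tests, the rule for named genes and 48 lists of 1038 genes, of which 951 had a probe set of their own, were fixed before the data were examined. The 47 lists other than the sex-linked genes were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives, with adjustment over the lists. With an estimated correlation camera tests on the 2 residual degrees of freedom, so it could hardly call a list here after adjustment. The rule named, for each direction, the 10 genes with the largest change past the adjusted threshold and, where there were fewer, those with the smallest p at a fold of at least 1.2 and no overlap of the groups. It further named 4 members of each called list, 1 member of each other response list and the sex-linked genes. Predicted genes, olfactory and vomeronasal receptors and small RNA genes were left out of the first part of the rule, which passed over 7 small RNA genes lower in ethanol and no gene of the other kinds.

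The fit was tested on simulated data with 2 against 2 arrays, 19938 genes and 50 genes changed at each of 4 fold sizes. At an adjusted p under 0.05 it recovered 0% of genes changed 1.2-fold, 48% at 1.5-fold, 92% at 2-fold and 96% at 4-fold, with 5 unchanged genes called. The rule without adjustment recovered 44% at 1.2-fold and also took 462 unchanged genes. A list shifted by -0.20 was called, and 0 other lists were. The simulated genes varied independently of each other, while the real mitosis list had an estimated correlation of 0.91. The simulation therefore does not show how often the list test errs on genes that vary together. Its recovered shares likewise hold for arrays without pool differences that many genes share. The rule without adjustment took 462 unchanged genes there, while 203 genes in all met it in the real data. Alternatives were other units of testing, other scalings, a filter on dim genes, other variance models, a block for the replicate number, other list tests, leaving out each array and other groupings of the arrays. Most of these were likewise fixed beforehand.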

Results

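Gene expression was measured in whole brains of C57BL/6J mouse fetuses, an inbred laboratory strain, at embryonic day 16. The pregnant females had been injected on gestational days 14 and 16 with ethanol at 2.5 g per kg or with saline alone. The comparison asks which transcripts differ in the fetal brain after this acute exposure. RNA of 3 mice was pooled for each array. From 12 mice in all, 2 ethanol pools and 2 control pools were hybridised to Affymetrix whole-transcript arrays, which read a transcript with several probes along its length. The median deposited log2 value was 8.04 and 8.01 on the 2 ethanol arrays and 8.04 and 8.01 on the 2 control arrays. The number of arrays limits the precision, and the median standard error of a log2 difference over the 19938 genes tested was 0.079. Which litters entered which pool is not given in the sources used here, so p-values of single genes measure only the spread between these pools. The list p-values at the preset correlation do not measure that spread. They set the members of a list against the other genes and take genes as nearly independent.

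The pools differed from each other within a group in muscle genes and in sex-linked genes. Over 12 skeletal muscle genes of the list of non-neural tissue genes, among them the actins Acta1 and Actc1 and the embryonic myosin Myh3, the median log2 level was 7.45 in ethanol 1, 8.59 in ethanol 2, 10.1 in control 1 and 7.38 in control 2. Control 1 exceeded control 2 by a median of 3.02, with 10 of the 12 genes at least 2-fold higher, and ethanol 2 exceeded ethanol 1 by 0.98, with 6 of the 12 at least 2-fold higher. Actc1 stood at 8.08, 11.2, 12.6 and 8.15 in ethanol 1, ethanol 2, control 1 and control 2. Of the 7 cartilage and 7 epithelial genes of that list, 0 were 2-fold higher in control 1 than in control 2 or in ethanol 2 than in ethanol 1. The cartilage genes had medians of 0.35 and 0.34 in these 2 differences, in the same direction as the muscle genes, and the epithelial genes -0.04 and -0.03. Xist, the RNA that silences an X chromosome in females, stood at 12.0 in ethanol 1, 12.8 in ethanol 2, 6.10 in control 1 and 12.8 in control 2. The Y-linked genes Eif2s3y, Kdm5d and Uty were lowest in control 2 and highest in control 1, with Eif2s3y at 9.98 and 11.6 in those pools and at 11.2 and 10.0 in ethanol 1 and ethanol 2. The mean of Xist was higher in ethanol by 2.91 ± 2.02 (log2, SE), a difference that rests on control 1. Over all genes, the SD of the log2 difference between 2 arrays was 0.217 for the 2 control pools and 0.168 for the 2 ethanol pools, against 0.133 to 0.251 for pairs of an ethanol and a control pool.

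**Figure D1:**
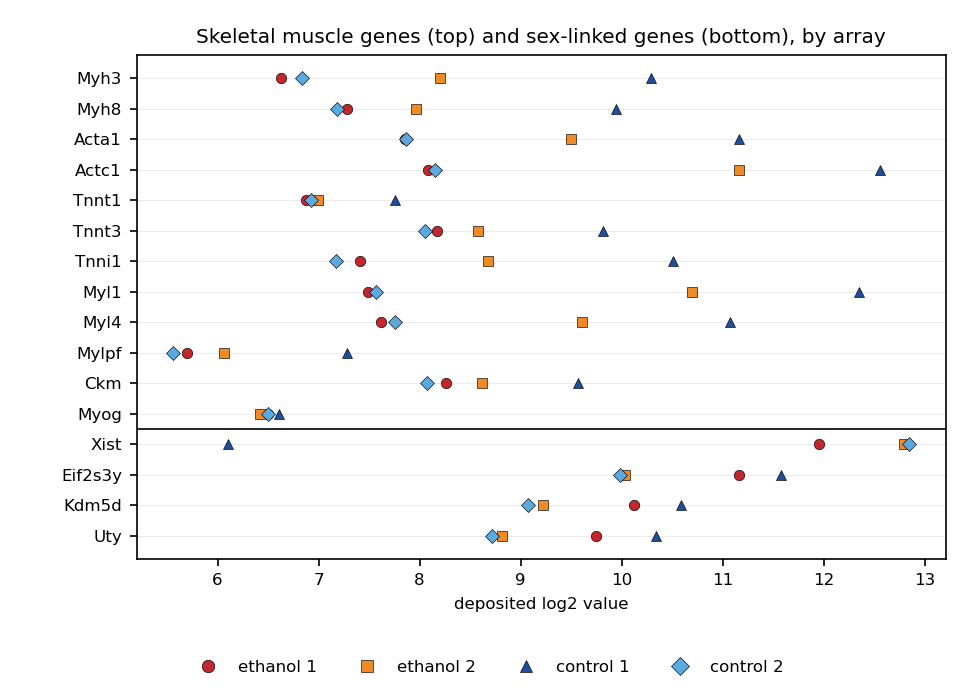
Deposited log2 value on the horizontal axis for 12 skeletal muscle genes (above the line) and 4 sex-linked genes (below the line), with 1 symbol per array. Control 1 has the highest muscle gene values, followed by ethanol 2 in most of these genes, and control 1 stands apart in Xist at 6.10 against 12.0 to 12.8 on the other arrays.

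Among the genes higher in ethanol with the smallest p, Slitrk2 (probe set 10599884), a synaptic adhesion protein of neurons, had a log2 difference of 0.51 ± 0.09 (SE, 2 arrays per group). Rybp, a subunit of Polycomb repressive complexes, was higher by 0.43 ± 0.08, and Gpr50, an orphan receptor related to the melatonin receptors, by 0.42 ± 0.07. Zfp600 (a zinc finger gene), Dusp19 (a dual-specificity phosphatase), Rnasek (a ribonuclease), Cptp (a ceramide-1-phosphate transfer protein), Lair1 (an inhibitory receptor of leukocytes), Pcdhb17 (a clustered protocadherin) and AI837181 were higher by 0.30 to 0.44. Among the genes lower in ethanol, Uqcr11 (probe set 10359826), a subunit of respiratory complex III, stood at -0.64 ± 0.12, and Uqcc2, an assembly factor of the same complex, at -0.47 ± 0.11. Cisd1, an iron-sulfur protein of the mitochondrial outer membrane, stood at -0.57 ± 0.12, and Ciapin1, of the cytosolic iron-sulfur assembly pathway, at -0.57 ± 0.13. Ptgds, the prostaglandin D synthase of meninges and choroid plexus, was lower by a log2 value of -0.42 ± 0.10. Tmem109, Dnal4 (a dynein light chain), Jmy (an actin nucleator and p53 cofactor), Cmbl and Pip5k1b (a phosphoinositide kinase) lay between -0.47 and -0.29. The naming rule took only genes in which both ethanol arrays lay on the same side of both control arrays, so this holds for all 20 by selection.

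None of these differences passed the test over all genes. Limma called 0 of 19938 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.980. At an unadjusted p under 0.05 there were 587 genes, where chance would give 996.9, and the ordinary test without shared variance called 0 genes adjusted and 768 unadjusted. A fold of at least 1.2 together with an unadjusted p under 0.05 was met by 203 genes, 96 higher and 107 lower in ethanol. The count was 1205 without ethanol 2 (792 higher, 413 lower) and 1265 without control 2 (383 higher, 882 lower), so the balance of directions turned with the array left out. After repeated quantile normalization 111 were higher and 83 lower. It came to 80 and 726 in the 2 groupings that mix ethanol and control pools. Both ethanol arrays lay outside the range of both control arrays in 6252 genes, or 31.4%, where chance gives 33.3%. Slitrk2 has a second probe set with a log2 difference of 0.01, while the second probe sets of Rybp, Uqcr11 and Uqcc2 went the same way as the first, at 0.24, -1.02 and -0.25. Without control 2 the only control pool left is control 1, low in Xist and highest in the muscle genes. The log2 difference of Xist was then 6.28. For 3 genes outside the naming rule it was -1.74 (Myoz1), -1.94 (Apobec2) and -2.10 (Cd36), named after their values were seen.

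**Figure D2:**
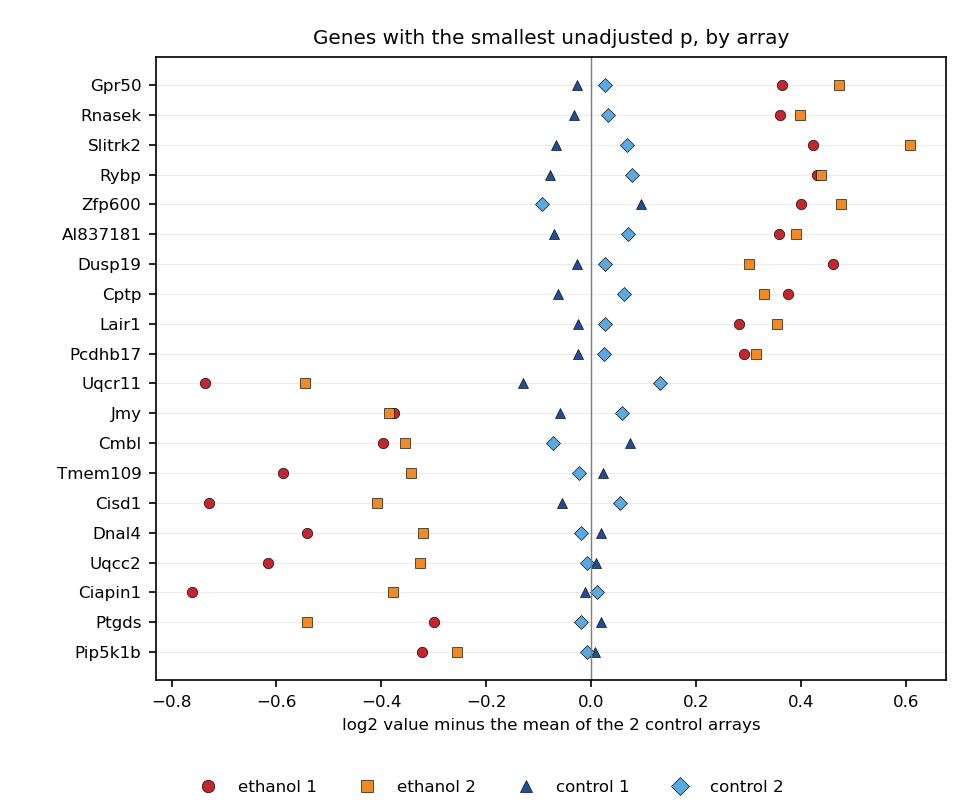
Log2 value minus the mean of the 2 control arrays on the horizontal axis for the 10 genes higher and the 10 genes lower in ethanol that the naming rule gave, with 1 symbol per array. By that rule both ethanol arrays lie apart from both control arrays in every gene shown, and no gene passed the adjusted test.

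Gene lists of cell division and of vessels and their coverings lay lower in ethanol than the other genes in the camera test with a preset correlation of 0.01. With an estimated correlation none of these 4 lists was called (adjusted p = 0.797 for each). That test rests on 2 residual degrees of freedom and could hardly call any list, so it cannot decide for or against these shifts. All 23 mitosis genes had a value below 0 (median log2 difference -0.13, adjusted p = 0.000236 at the preset correlation and adjusted p = 0.797 with an estimated correlation). Top2a, the topoisomerase of dividing cells, stood at -0.27 ± 0.20 (a second probe set at -0.21), Bub1b, a spindle checkpoint kinase, at -0.25 ± 0.18, the cyclin-dependent kinase Cdk1 at -0.25 ± 0.18 and cyclin Ccnb2 at -0.24 ± 0.14. Of 25 genes of DNA replication, 23 were below 0 (median -0.10, adjusted p = 0.000236). The polymerase subunit Pola1 stood at -0.33 ± 0.12 and the replicative helicase subunits Mcm6 at -0.31 ± 0.12 and Mcm2 at -0.25 ± 0.13, and the ligase Lig1 at -0.16 ± 0.09. Of 22 pericyte, fibroblast and meningeal markers, 21 were below 0 (median -0.21, adjusted p = 0.000236). The aminopeptidase Anpep stood at -0.50 ± 0.25, Ptgds as given, the retinoic acid synthesis enzyme Aldh1a2 at -0.21 ± 0.16 and the basement membrane collagen Col4a1 at -0.18 ± 0.13. Of 20 endothelial markers, 18 were below 0 (median -0.13, adjusted p = 0.000308). The tight junction protein Cldn5 stood at -0.17 ± 0.07, the angiopoietin receptor Tek at -0.19 ± 0.08, the thyroid hormone transporter Slco1c1 at -0.21 ± 0.09 and the phosphatase Ptprb at -0.21 ± 0.09. Control 1, the pool with the highest muscle gene levels, was the highest array in each of these 4 lists. The mitosis median was -0.41 for ethanol 1 against control 1 and 0.15 for ethanol 2 against control 2, and the pericyte median was -0.69 and 0.20 in those pairs. Without control 1 the medians turned above 0 for mitosis (0.034), replication (0.009) and pericyte (0.072) genes, and that of the endothelial markers came to -0.01 with its call lost. Without ethanol 1 the mitosis (median -0.07), replication (median -0.02) and pericyte (median -0.09) lists lost their calls. Among the brighter genes the pericyte list lost its call (adjusted p = 0.0612) at a median of -0.21.

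Smaller shifts below 0 were called for 5 further lists at the preset correlation, and with an estimated correlation all 5 had an adjusted p of 0.797. Of 32 DNA methylation and chromatin modifier genes, 28 were below 0 (median -0.06, adjusted p = 0.00228). The chromatin remodeller Chd7 stood at -0.23 ± 0.09 (29 further probe sets from -0.42 to 0.03, median -0.16), the deacetylase Hdac3 at -0.15 ± 0.08, the histone methyltransferase Ehmt2 at -0.14 ± 0.08 and the methyl-CpG binding protein Mbd1 at -0.12 ± 0.07. Of 25 ribosomal protein genes, 20 were below 0 (median -0.08, adjusted p = 0.00228). Rpl4 stood at -0.18 ± 0.08, Rpl14 at -0.18 ± 0.08, Rplp2 at -0.17 ± 0.07 and Rplp0 at -0.16 ± 0.08 (a second probe set at -0.08). Of 23 NOTCH pathway genes, 17 were below 0 (median -0.07, adjusted p = 0.00453). The signalling antagonist Numb stood at -0.22 ± 0.07, the receptor Notch3 at -0.22 ± 0.08, the target Hey1 at -0.22 ± 0.10 and the ligand Dll1 at -0.18 ± 0.09. Of 34 axon guidance and adhesion genes, 29 were below 0 (median -0.04, adjusted p = 0.0101). The receptor Plxnd1 stood at -0.20 ± 0.10, the ephrin Efnb2 at -0.19 ± 0.09, the guidance cue Slit3 at -0.16 ± 0.11 and the netrin receptor Unc5c at -0.09 ± 0.07. Of 24 hypoxia-inducible genes, 17 were below 0 (median -0.05, adjusted p = 0.0293). The oxygen sensor Egln3 stood at -0.20 ± 0.09, lactate dehydrogenase Ldha at -0.16 ± 0.08 and adrenomedullin (Adm) at -0.14 ± 0.07, while Ankrd37 stood at 0.13 ± 0.07. The axon guidance list was the only one of these 5 that kept its call without control 1 (adjusted p = 0.0248), and the hypoxia median then came to 0.005. The medians of the chromatin, ribosomal and NOTCH lists shrank to -0.00845, -0.0099 and -0.04 without control 1. Without ethanol 1 none of the 5 kept its call (adjusted p = 0.445 for axon guidance), and the axon guidance list also lost it without control 2 (adjusted p = 0.124). After repeated quantile normalization the axon guidance (median -0.02, adjusted p = 0.107) and hypoxia (median -0.06, adjusted p = 0.0819) lists were not called. Among the brighter genes, where fewer members enter, none of the 5 was called. Their medians there were -0.06 for chromatin, -0.08 for ribosomal, -0.14 for NOTCH, -0.04 for axon guidance and -0.06 for hypoxia genes.

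Above the other genes lay 3 lists at the preset correlation, and with an estimated correlation all 3 had an adjusted p of 0.797. Of 23 inflammatory cytokine and NF-kB genes, 19 were above 0 (median 0.07, adjusted p = 0.00525). The chemokine Ccl3 stood at 0.29 ± 0.07, the chemokines Cxcl10 and Ccl5 at 0.23 ± 0.08 and 0.21 ± 0.08, and the cytokine Il1b at 0.19 ± 0.12. Of 13 thalamic neuron markers, 11 were above 0 (median 0.10, adjusted p = 0.0128). Among transcription factors, Shox2 stood at 0.20 ± 0.08, Gbx2 at 0.14 ± 0.07, Tcf7l2 at 0.13 ± 0.08 and Foxp2 at 0.12 ± 0.08. Of 18 HOX-domain genes of hindbrain and spinal cord, 15 were above 0 (median 0.08, adjusted p = 0.0272). Hoxb5 stood at 0.67 ± 0.34, Hoxc4 at 0.18 ± 0.07, Hoxd4 at 0.16 ± 0.08 and Hoxa7 at 0.13 ± 0.07. The log2 levels of Hoxd4 (5.94 to 6.23) and Hoxa7 (6.25 to 6.44) lay below the lower quartile of each array (6.45 to 6.55). Cxcl10 (6.13 to 6.47) also did, and Il1b (6.18 to 6.56) did on all arrays but ethanol 1. The HOX median was 0.22 for ethanol 2 against control 2 and -0.08 for ethanol 1 against control 1. The HOX list lost its call without ethanol 2 (median 0.03, adjusted p = 0.976) and without control 2 (median 0.009, adjusted p = 0.865), after repeated quantile normalization (adjusted p = 0.101) and among the brighter genes (adjusted p = 0.360). Without ethanol 1 the inflammatory median was 0.02 and the list was no longer called, while the thalamic list was not called without control 1 (adjusted p = 0.399) or ethanol 2 (adjusted p = 0.144). Fry called 0 of 47 lists (smallest adjusted p 0.931, 1 list at an unadjusted p under 0.05). No member of any list passed when adjusted over the list alone or over all genes. The number of lists called, 12 of 47 with all arrays, was 5 without ethanol 1 and 21 without control 2. The balance of 3 higher and 9 lower turned to 8 higher and 3 lower without control 1 and to 4 higher and 1 lower without ethanol 1. The 2 groupings that mix ethanol and control pools gave 9 and 24, of which 2 and 9 were among the 12. Most of the 12 lists were thus also called in a grouping that does not separate ethanol from control.

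**Figure D3:**
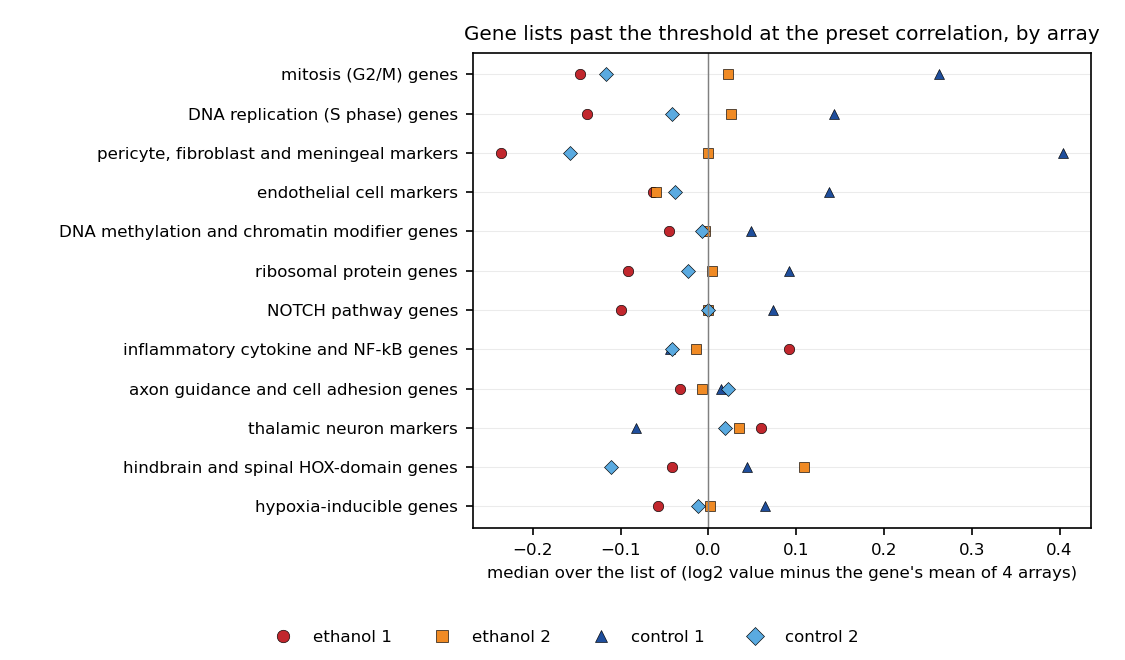
Median over each list of the log2 value minus the gene's mean of the 4 arrays, on the horizontal axis, for the 12 lists past the threshold at the preset correlation, with 1 symbol per array. Control 1 is the highest array in 8 of the 9 lists lower in ethanol.

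The other 35 lists were not called, with medians from -0.08 to 0.06 and a lowest adjusted p of 0.0520, for choroid plexus and ependymal markers (median -0.07). The neural cell type lists included radial glia (20 genes, median 0.001), general neuronal markers (21 genes, median 0.003), deep-layer cortical neurons (14 genes, median -0.01), upper-layer neurons (13 genes, median -0.04), astrocytes (14 genes, median -0.04) and oligodendrocyte lineage markers (14 genes, median 0.04). Among the response lists, the genes of alcohol and aldehyde metabolism had a median of 0.002, and Aldh2, the main mitochondrial acetaldehyde-oxidising enzyme, stood at -0.23 ± 0.12. Mitochondrial oxidative phosphorylation genes had a median of -0.01, and the complex II subunit Sdhd stood at -0.23 ± 0.07. Cycs, the cytochrome c gene in the apoptosis list (median -0.01), stood at -0.51 ± 0.15, with 2 further probe sets at -0.44 and 0.01. The transcription factor Jun stood at -0.33 ± 0.09 in the immediate early list (median 0.04), the steroid pathway enzyme Hsd17b7 at 0.27 ± 0.07 in the cholesterol list (median 0.02), and Ddit4, a stress-inducible inhibitor of mTORC1, at 0.24 ± 0.09 in the glucocorticoid list (median -0.05). The remaining examples were the chaperone Hspa1a at 0.23 ± 0.12 in the heat shock list (median -0.06) and the glutathione transferase Gstm1 at 0.29 ± 0.13 in the oxidative stress list (median -0.02). The p53 target Plk3 stood at 0.19 ± 0.07 (list median -0.02) and the chaperone Dnajb9 of the endoplasmic reticulum at 0.17 ± 0.08 (list median -0.02). The interferon-induced Ifit3 stood at 0.16 ± 0.07 (list median 0.02) and the clock output gene Hlf at -0.16 ± 0.09 (list median 0.04). None of these genes passed the adjusted test.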

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

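Leaving out an array, the groupings of pools and the scalings were planned, while crossed pairing and the mixed groupings for genes and lists called were chosen after the data were seen. The count of genes past the adjusted threshold stayed at 0 under all alternatives except leaving out an array (0 to 4) and the grouping of ethanol 1 and control 2 against the others (3). The 203 genes past the relaxed rule became 993 over all probe sets, where control probe sets are included since the files do not mark them. They became 134 in the brighter genes, 37 in the ordinary test, 3 at a fold of 1.5 and 80 and 726 in the mixed groupings. With an array left out they ranged from 142 to 1265. The 6252 genes with groups apart became 11200 over all probe sets and 3466 in the brighter genes, where fewer genes enter. The 12 called lists became 6 in the brighter genes, of which 4 were among the 12, while 7 of the 12 lost their call and the inflammatory list had too few genes left. They became 0 with an estimated correlation (adjusted p = 0.797 for each), a test with too few degrees of freedom to call lists here. They became 0 by fry (1 list at an unadjusted p under 0.05) and 24 in the grouping of ethanol 1 and control 2, with 9 of the 24 among the 12. With an array left out they ranged from 5 to 21. Quantile normalization again, median centring, the mean of a gene's probe sets, and, for genes, trend and robust variances moved no count by over 1.5 times. After repeated quantile normalization 9 of the 12 lists kept their call and 3 lost it.

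The replicate numbers are not said to pair the arrays, and deviations of same-numbered arrays correlated at -0.484. With the replicate number as a block 0 genes were called, 196 passed the relaxed rule and 13 lists were called. With crossed pairing 0 genes, 373 genes by the relaxed rule and 16 lists were called, with 0 lists at an estimated correlation. A block leaves that last test still fewer degrees of freedom, so its count says little.

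With an array left out, medians ran from -0.33 to 0.034 for mitosis, -0.20 to 0.00923 for S phase, -0.52 to 0.072 for pericyte and -0.0884 to 0.00503 for hypoxia genes, each highest without control 1. Log2 differences ran from -0.37 to 0.0106 for Col4a1, -0.45 to 0.0236 for Aldh1a2, -0.47 to 6.28 for Xist. For the Y-linked genes they ran from -0.98 to 0.62 for Eif2s3y (0.39 without ethanol 2), -0.91 to 0.60 for Kdm5d (0.29) and -1.06 to 0.56 for Uty (0.22). The cause was not tested beyond what the other observations report. Of 980 alternative values of named genes, 971 kept their sign. This count is no measure of stability. The variance models, the ordinary test, the replicate block and the filter on dim genes leave a log2 difference unchanged. Genes named with groups apart also cannot turn when an array is left out. A lone array in a group was assumed to vary like the other group.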

Other observations

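Of the tests in this part, the comparison of the inflammatory list with expression-matched lists on the deposited values was set before its result was seen, and the others were chosen after the values were seen. The precursor miRNA genes of the imprinted interval between Dlk1 and Dio3 lay lower in ethanol. Of 40 such genes with a probe set, 34 had a lower mean in ethanol (median -0.13, range -0.46 to 0.05), and in 21, or 52.5%, both ethanol arrays lay below both control arrays, with 1 gene above. Mir379 stood at -0.46 ± 0.11 (log2, SE), Mir380 at -0.41 ± 0.07, Mir381 at -0.41 ± 0.09, Mir540 at -0.40 ± 0.08, Mir337 at -0.37 ± 0.07 and Mir665 at -0.35 ± 0.07, and no member passed the adjusted test over all genes. These genes fall outside the naming rule and were chosen after their values were seen. The long RNAs of the interval stood at -0.06 ± 0.07 for Meg3 and -0.04 ± 0.09 for Rian, and the protein-coding Dlk1 at -0.37 ± 0.41. The other genes of the interval stood at -0.24 ± 0.07 for DQ267101, -0.17 ± 0.08 for Rtl1, -0.12 ± 0.07 for DQ267102, -0.08 ± 0.07 for AF357341 and 0.02 ± 0.07 for Dio3. The median of these 8 genes was -0.10, and whether the miRNA genes differ from them was not tested. The median was -0.17 to -0.14 in the 4 pairs of an ethanol and a control array, -0.17 to -0.12 with an array left out, and -0.15 and -0.13 under the 2 other scalings. Camera gave the set p = 0.0164 with an estimated correlation, a value for a set picked from these data, whose members share host transcripts and are not independent.

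For the miRNA interval, a uniform shift of all miRNA probe sets is argued against by the other 256 miRNA genes, whose median was 0.038. Those genes were not matched to the interval on level (mean log2 8.74), and the dimmest genes had a similar median of 0.042. They therefore cannot tell whether brighter small RNA genes were lower more broadly. By the relaxed rule with groups apart, 20 small RNA genes were lower and 2 higher, with 10 of the 20 in the interval. The sex composition of the pools is argued against by 1 pair of arrays only, ethanol 2 against control 2, pools close in Xist and Y-linked levels. The median there was -0.136 ± 0.026 (SE over members, which are not independent). That SE holds no spread between pools. Non-neural tissue content is argued against by the grouping of ethanol 1 and control 2 against the pools with more muscle RNA, where the median was -0.024 ± 0.024, closer to 0 than the set bound of -0.067. At a margin of 2 standard errors that value would exclude nothing. Of the 3 groupings, 1, the real one, gave a median this far from 0 (-0.13, against 0.024 in size for the highest other), which is too few groupings for a share under 0.05. An effect of ethanol on this interval stays open as a hypothesis, as do litter differences and a broader difference in small RNA between pools.

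At the preset correlation 9 lists were lower in ethanol, with a median of -0.076 over their list medians, and 3 were higher. Without control 1 this median came to -0.00845, with 4 list medians above 0 and 5 still below and with 8 lists called higher and 3 lower, which leaves open whether a control pool with other tissue content may account for the direction. A plain dilution of brain RNA in control 1 would lower neural lists alike. Radial glia markers had a median of 0.060 ± 0.041 (SE over members) in control 1 against control 2, while neuronal markers stood at -0.121 ± 0.022. This sets 1 array against 1 array, so the SE holds no spread between pools. The radial glia value lay above 0 at the set margin of 1 standard error but not at 2. Sox9 is in both the radial glia and the non-neural list, so added non-neural RNA may raise members of the radial glia list. The values therefore cannot decide on dilution, which stays open. Differences in age or dissection between pools, and an effect of ethanol on dividing cells, stay open and were not tested apart from control 1.

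The inflammatory list was higher in ethanol, with a median of 0.071. Random lists matched on mean expression gave medians from -0.006 to 0.074 in their central range, and the list stood at percentile 96.2 among 10000 of them, so higher values of dim genes, with the lower quartile raised on ethanol 1 alone, may account for it. The list itself stood at 0.09 on ethanol 1 against the mean of the arrays and at -0.01 on ethanol 2, and it was not called without ethanol 1. Repeated quantile normalization took its median to 0.054 ± 0.018 (SE over members), at percentile 98.3 of matched lists whose central range ended at 0.052, with an adjusted p of 0.0316 at the preset correlation and 0.818 with an estimated correlation. That margin is within the spread of the members, so scaling of the dim end of ethanol 1 and an inflammatory response to ethanol both stay open.

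In the grouping of ethanol 1 and control 2 against ethanol 2 and control 1, 3 genes passed limma's adjusted threshold, at -3.74 for Ibsp (bone sialoprotein), -2.66 for Oc90 (an otoconial protein of the inner ear) and -1.71 for Col1a1 (a collagen of bone and connective tissue), named after their values were seen. That grouping gave 1770 genes at an unadjusted p under 0.05, against 587 in the real one and 265 in that of ethanol 1 and control 1 against the others. It sets apart ethanol 2 and control 1, the pools with the higher muscle gene medians (8.59 and 10.1, against 7.45 in ethanol 1 and 7.38 in control 2). This points to a structure of the samples, and whether tissue content accounts for it was not tested further. Among the small RNA genes that met the relaxed rule with groups apart, 20 were lower and 2 higher in ethanol, and 10 of the 20 are the miRNA genes between Dlk1 and Dio3 already described. Of the 256 miRNA genes elsewhere, 102 were lower in ethanol (median 0.038). Among olfactory and vomeronasal receptor genes 12 were higher and 1 lower by that rule. Of all 1194 receptor genes, 967 were higher in ethanol (median 0.068), against 798 (median 0.034) after quantile normalization again and 989 (median 0.074) after median centring.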
